A study of Mus musculus with 6 samples.

How the data were processed

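RNA levels were measured in mouse pluripotent stem cells on 6 Affymetrix arrays, 3 of induced pluripotent stem (iPS) cells and 3 of embryonic stem cells made by nuclear transfer (ntES). Per the labels' protocols, total RNA was taken with Trizol from cultures on mitomycin C-treated mouse embryonic fibroblast feeders, and was labelled with biotin through a WT Terminal Labeling Kit. The arrays were read with GCOS 1.4, per the submitters' processing notes. The background correction, normalization, probe set summary and genome build behind the deposited values are not given in the sources used here.

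The deposited table held log2 expression values of 23344 probe sets, a scale taken from the values themselves, which ran from 3.6 to 13.7. The medians of the 6 arrays lay between 7.61 and 7.70, within 0.088 of each other. This was under the limit of 0.1 set beforehand for testing the deposited log2 values without further scaling. The SD over probe sets differed more, from 1.51 on ntES replicate 1 to 1.74 on ntES replicate 3, so the arrays did not share one distribution. No 2 arrays held the same values throughout: the most alike pair had equal values, to 6 decimals, at 864 of the 23344 probe sets, and the lowest correlation within a group was 0.994. The number of arrays limits the precision.

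Probe sets were named from the platform annotation that came with the table. It gave 1 gene symbol for 20746 probe sets and several for 1183, and did not list 1415. Of the probe sets with 1 symbol, 20702 were matched through the gene identifier to the GRCm38.p6 gene table, and no symbol needed updating. No gene was named from a probe set with several symbols. The 20746 probe sets stood for 19308 genes, of which 807 had 2 or more, and a gene was then represented by its probe set of highest mean over the 6 arrays. Probe sets with 1 symbol can still bind transcripts of close gene copies, so members of families such as Usp17l, Tdpoz and Pramel are uncertain as single genes. Whether the brightest probe set reads the gene itself or a copy was not checked. This bears on genes such as Dppa3 and Idi1, whose other probe sets changed less.

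The groups came from the sample titles. The 1 comparison was ntES minus iPS, fitted to all 23344 probe sets with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, without covariates and with Benjamini-Hochberg adjustment. A probe set was called at an adjusted p under 0.05, and a second count also asked for a 2-fold change, a log2 difference of 1 or more in size. Adjusted p values of single genes in the text are limma's, and errors are standard errors of the difference (SE) or standard deviations over 3 arrays (SD). The fold change of a dim probe set is understated where background adds to its signal.

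There were 29 gene lists, on pluripotency, telomeres, repair, mitochondria, metabolism, imprinting, germ line, lineages, feeder and immune cells, and stress. They named 856 different genes, of which 720 were measured, and 28 lists had a measured member. Each list was compared with all other genes by limma's camera, two-sided, with the inter-gene correlation preset at 0.01, with Benjamini-Hochberg adjustment over the lists. Camera was run again with the correlation estimated for each list, and fry, which asks whether the genes of a list move one way on balance, was run beside it. List members were counted by their adjusted p over all probe sets and also adjusted over the list alone.

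The groups, tests, thresholds, gene lists, 15 of the alternative settings and the rule for naming genes were fixed before the data were examined. The rule took the 12 largest rises and the 12 largest falls among called probe sets with 1 symbol whose groups did not overlap. For each list it took up to 4 called members with the largest change, or the 2 with the smallest p. It also took a set of fixed genes, of which Zscan4c, Tcstv1 and Ddx3y were not analysed here. The alternatives were quantile normalization, median centring, leaving out dim probe sets, leaving out probe sets without 1 symbol, a variance trend with robust priors, array weights, a replicate block, an unmoderated linear-model test, a stricter threshold of 0.01, and leaving out each replicate in turn. For the lists they also included an estimated correlation and the mean of all probe sets of a gene. The log transform planned for linear values was not needed.

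The medians of neighbouring genes were examined after the first results were seen. The 9669 genes with a mean at or above the median probe set and a place in the GRCm38.p6 gene table were put in gene order. Differences were centred within 10 brightness classes, and running medians over 41 genes were compared with the 95th percentile of the largest running median in 1000 permutations within those classes. The gene table served only for the order of genes, since the build behind the array values is not given in the sources used here. Figures and these steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

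The fit was tested on simulated data made from the 23344 probe sets, with 200 of them changed between ntES and iPS in each of 10 runs. It recovered 84.6% of changes of 0.5 on the log2 scale with 5.7% of calls false, and 100% of changes of 1 with 6% false. The simulated noise was drawn independently for each probe set. On the real arrays deviations from the group means were shared across probe sets, with a correlation of 0.69 between iPS replicate 3 and ntES replicate 1. The simulated shares therefore need not hold for the real arrays.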

Results

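Gene expression was compared between ntES cells and iPS cells that had both been made from tail-tip fibroblasts of generation 3 telomerase-deficient (G3 Terc-/-) mice. Terc is the RNA template of telomerase, and mice bred for generations without it have short telomeres. In nuclear transfer a somatic nucleus is reprogrammed by an egg, whereas iPS cells arise from somatic cells that are given reprogramming factors. The study, by its title, asked how reprogramming bears on the telomere and mitochondrial defects of such cells. Each group had 3 arrays, described as biological repeats of a cell line, so that p-values measure the spread between these samples. If each group is 1 line, the line and the reprogramming method cannot be told apart. Arrays of 1 group correlated at 0.994 or higher, and arrays of different groups at 0.983 to 0.988. The leading principal component held 59.0% of the variance and separated the groups, and the next held 30.5% and separated arrays within both groups.

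In ntES cells 13 of 15 measured genes of the 2-cell-like state rose, as did the epithelial keratins Krt8 and Krt18, 11 of 39 fibroblast markers and 7 of 23 endoderm markers. In the other direction, 9 of 23 interferon response genes, 6 of 21 genes of cholesterol and lipid synthesis and 7 of 35 pluripotency genes fell, while the core pluripotency factors Pou5f1, Sox2 and Nanog did not pass the test. These lists passed camera's test with a preset correlation, and none passed with an estimated correlation, where the adjusted p of called lists lay between 0.224 and 0.965. Obox6, an oocyte-type homeobox gene, was 9.22-fold higher in ntES cells, and Irgm1, an interferon-induced GTPase of cell-autonomous defence, was 4.24-fold higher in iPS cells. Imprinted genes changed in both directions, with Zdbf2 4.60-fold higher in ntES cells and Mest 2.53-fold higher in iPS cells. Genes that fell often lay side by side on a few chromosome segments.

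In all, 2643 of 23344 probe sets passed an adjusted p of 0.05, 1212 higher and 1431 lower in ntES cells, and 137 of these also changed 2-fold, 84 higher and 53 lower. The called probe sets covered 1048 named genes that rose and 1232 that fell. At an unadjusted p under 0.05 there were 5736 probe sets. Quantile normalization raised the count to 7035, with 2610 of the 2643 among them, while the 2-fold count was 133. Centring each array on its median turned the split into 823 higher and 1911 lower, or 30.1% higher in place of 45.9%.

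The largest rises included Obox6, at 6.70 ± 0.15 in iPS and 9.91 ± 0.45 in ntES cells (log2, mean ± SD, n = 3 each; adjusted p = 1.12e-05, limma). Srgn, the core protein of granule proteoglycans, rose by 2.91 ± 0.14 (log2, SE), and Cth, which makes cysteine from cystathionine, by 2.23 ± 0.12. Mcf2 rose by 2.18. The zinc finger genes Zfp640, Zfp352 and Zfp991 rose by 2.03, 1.90 and 1.78, and the germ-line piRNA factor Tdrd12 rose by 1.73. Among the largest falls, Irgm1 went from 9.58 ± 0.16 in iPS to 7.50 ± 0.16 in ntES cells (log2, mean ± SD, n = 3 each; adjusted p = 7.58e-06, limma). The metal transporter Slc39a8 changed by -1.85 and the amino acid transporter Slc6a14 by -1.68. Gstz1, an enzyme of tyrosine breakdown, changed by -1.47, and Coa8, an assembly factor of cytochrome c oxidase, by -1.42. C2cd5, the neuronal calcium-binding gene Necab1, the arginine methyltransferase Prmt8, and the interferon-induced Oas2 and Rnf213 changed by -1.49, -1.32, -1.30, -1.35 and -1.33.

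**Figure D1:**
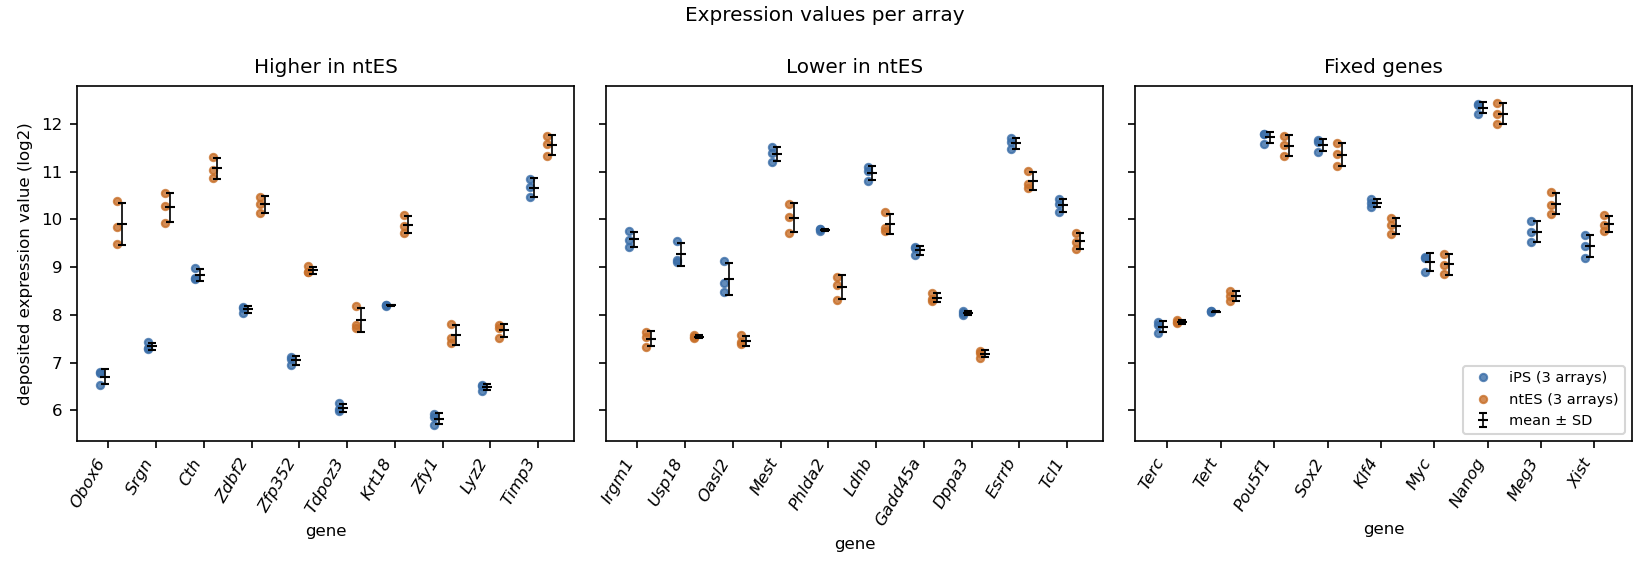
Deposited expression values (log2, vertical axis) of named genes on each of the 3 iPS arrays (blue) and 3 ntES arrays (orange), with the mean ± SD beside each group. The groups do not overlap for the genes of the left and middle panels, such as Obox6 and Irgm1, while in the right panel Pou5f1, Sox2, Myc and Nanog overlap.

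The deleted gene came first among the genes fixed in advance. The Terc probe set read between 7.62 and 7.90 on all 6 arrays, with a difference of 0.10 ± 0.09 (log2, SE; adjusted p = 0.502). There was no array of cells with Terc, and it is not known here whether the probes lie in the deleted part, so this value checks no label. Of the reprogramming factors, Klf4 fell by 0.47 (adjusted p = 0.0134). It did not pass without iPS replicate 1 (0.0706), iPS replicate 2 (0.0867) or ntES replicate 2 (0.0738), or with the unmoderated test (0.124). Pou5f1, Sox2 and Myc differed by -0.18, -0.21 and -0.05 with adjusted p of 0.389, 0.344 and 0.842. Nanog differed by -0.12 (adjusted p = 0.558). After quantile normalization Pou5f1, Sox2 and Nanog passed, at -0.17, -0.21 and -0.13. Tert, the protein subunit of telomerase, rose by 0.32 (adjusted p = 0.0293). It did not pass after median centring, at 0.27 with an adjusted p of 0.067, with the replicate block (0.135) or with the unmoderated test (0.0808). Nor did Tert pass without iPS replicate 1, 2 or 3 or ntES replicate 2, where the adjusted p lay between 0.086 and 0.152. It lay at the end of a jointly higher segment of chromosome 13, from Zfp935 to Tert, with a median of 0.22. That segment was only as long as the window of 41 genes. It was not found again when segments were sought from every other gene alone. Meg3, an imprinted noncoding RNA, rose by 0.59 ± 0.14 (log2, SE; adjusted p = 0.0202). It did not pass without iPS replicate 2 (0.0863), iPS replicate 3 (0.0675) or ntES replicate 2 (0.0848), or with the unmoderated test (0.208). The fibroblast marker Postn rose as well, by 0.74.

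Genes that are active in 2-cell embryos and in a rare 2-cell-like state of embryonic stem cells rose most often among the lists. The list named 33 genes, of which only 15 were measured. Of these 15, 13 rose and none fell (14 and 0 adjusted over the list alone), with a median difference of 0.97. Zfp352, Tdpoz3, Gm5662 and Usp17lc rose by 1.90, 1.85, 1.69 and 1.02. Camera gave an adjusted p of 1.12e-16, and the adjusted p = 0.224 with an estimated correlation. In iPS cells these 4 genes read below the median probe set of 7.66, with Zfp352 at 7.05, and in ntES cells above it, with Zfp352 at 8.94. Of 29 germ-line genes, 4 rose and none fell (5 and 0 adjusted over the list alone), among them Hormad1, a meiotic chromosome axis gene, by 0.45 and Tex19.1 by 0.34, and the list did not pass (adjusted p = 0.376).

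Of 35 pluripotency genes, 7 fell and none rose (10 and 2 adjusted over the list alone). Dppa3, a maternal factor that guards DNA methylation, Esrrb and Prdm14, transcription factors of the naive state, and Tcl1, a coactivator of Akt, changed by -0.86, -0.79, -0.74 and -0.75, and another probe set of Dppa3 differed by -0.40. In the same comparison 36 of 39 fibroblast and feeder markers lay above 0, with a median of 0.29. By camera the pluripotency list was lower in ntES cells (adjusted p = 0.00246), with an adjusted p = 0.965 with an estimated correlation. The pluripotency list did not pass without ntES replicate 1 (adjusted p = 0.135) or without dim probe sets (adjusted p = 0.211). Esrrb and Tcl1 lay in a chromosome segment whose genes were jointly lower. Of 22 primed epiblast genes, 6 rose and 4 fell (6 and 6 adjusted over the list alone; adjusted p = 0.984). Otx2, which drives exit from the naive state, rose by 0.82, and Lef1 and Zic2 changed by -1.21 and -0.71. Krt18, also counted among the epithelial and trophectoderm genes, rose by 1.69.

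Interferon response genes had more falls than any other list by the adjusted p over all probe sets, though not adjusted over the list alone. Of 23 measured, 9 fell and none rose (10 and 0 adjusted over the list alone), and 1 member lay above 0. Usp18, which removes the ubiquitin-like ISG15 from proteins, changed by -1.72, the oligoadenylate synthetase-like gene Oasl2 by -1.30, Ifit3 by -0.89 and Ifi27 by -0.85. Camera gave an adjusted p of 5.6e-10, and the adjusted p = 0.457 with an estimated correlation. Of 21 genes of cholesterol and lipid synthesis, 6 fell and none rose (11 and 1 adjusted over the list alone). The mevalonate pathway enzymes Mvd, Idi1 and Mvk and the lanosterol synthase Lss changed by -0.60, -0.58, -0.48 and -0.42, and another probe set of Idi1 differed by -0.13. This list had an adjusted p of 1.05e-05, and an adjusted p = 0.931 with an estimated correlation.

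Of 17 genes of shelterin and telomere capping, 4 fell and 1 rose (6 and 2 adjusted over the list alone). Acd, Terf2 and Pot1a, subunits of the complex that covers telomeres, changed by -0.55, -0.43 and -0.43, and Dclre1b, a telomeric nuclease named after its values were seen, by -0.42. Terf1, which binds telomeric double strands, rose by 0.62. The list was lower (adjusted p = 0.00503), with an adjusted p = 0.965 with an estimated correlation, and it did not pass without ntES replicate 1 (adjusted p = 0.0932) or without dim probe sets (adjusted p = 0.157). Of 12 telomerase components, Tert rose and none fell (1 and 0 adjusted over the list alone; adjusted p = 0.441). Of 31 genes of recombination and double-strand break repair, 3 fell and none rose (3 and 0 in the same directions, adjusted over the list alone). These were Xrcc3, Rad52 and Fanca, at -0.58, -0.45 and -0.40, and all 3 lay in jointly lower chromosome segments. That list passed at 0.0205, had an adjusted p = 0.965 with an estimated correlation, and did not pass after quantile normalization (adjusted p = 0.19) or with the genes of shifted segments left out (adjusted p = 0.208). It also did not pass without dim probe sets (0.372), without the 2 arrays of narrowest spread (0.133), or without iPS replicate 1 (0.0665), iPS replicate 2 (0.0712) or ntES replicate 1 (0.458).

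Among the mitochondrial lists none passed. Of 35 genes of respiratory complex I, 3 fell and none rose (3 and 0 in the same directions, adjusted over the list alone; adjusted p = 0.144), namely Ndufa9, Ndufa11 and Ndufv1 at -0.64, -0.57 and -0.56, with another probe set of Ndufa11 at -0.28. Of 39 genes of complexes II to V, 2 fell, Cox4i1 at -0.42 and Sdhc at -0.37 (0 adjusted over the list alone; adjusted p = 0.425). Of 28 genes of mitochondrial biogenesis and dynamics, 3 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.338). Pprc1, a coactivator of nuclear respiratory genes, Tomm20, an import receptor, and Tfb1m, an rRNA methyltransferase, changed by -0.72, -0.60 and -0.50, and the fusion protein Mfn2 rose by 0.41. Without ntES replicate 3 these lists passed as lower, at adjusted p of 0.00316 for complex I, 0.00476 for complexes II to V and 0.0472 for biogenesis and dynamics, and complex I also passed without iPS replicate 3 (adjusted p = 0.0204). The transcripts of the mitochondrial genome were not analysed here. Of 28 antioxidant genes, 3 rose and none fell (6 and 1 adjusted over the list alone; adjusted p = 0.196), with Gpx2, a glutathione peroxidase, up by 0.80, Srxn1 by 0.50 and catalase (Cat) by 0.50. The antioxidant list passed as higher after quantile normalization (adjusted p = 0.0377) and without ntES replicate 1 (adjusted p = 0.00399). Of 19 glycolysis genes, 2 fell and 1 rose (2 and 5 adjusted over the list alone; adjusted p = 0.984). Ldhb and the glucose transporter Slc2a3 changed by -1.05 and -0.59, and Pfkm rose by 0.54.

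Of 41 imprinted genes, 10 rose and 5 fell (12 and 7 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.142). Zdbf2 went from 8.11 ± 0.07 in iPS to 10.31 ± 0.17 in ntES cells (log2, mean ± SD, n = 3 each; adjusted p = 3.79e-06, limma). Rian, a noncoding RNA expressed with Meg3 from the maternal chromosome, rose by 0.96. Mest and Phlda2, a growth-restraining placental gene, changed by -1.34 and -1.20. Of 8 genes of X inactivation and the Y chromosome, 4 rose and none fell (4 and 1 adjusted over the list alone). The Y-linked Zfy1, Kdm5d and Uty rose by 1.76, 0.89 and 0.60, and Xist, the RNA that coats the inactive X, by 0.47. Xist did not pass after median centring (0.0793), without iPS replicate 2 (0.147) or 3 (0.126), or without ntES replicate 2 (0.15) or 3 (0.0653). It also did not pass with the unmoderated test (0.254) or with the genes of shifted segments left out (0.0516). The list had an adjusted p of 0.0136, an adjusted p = 0.52 with an estimated correlation, 0.376 without dim probe sets, and 0.0549 without ntES replicate 3. Of 26 genes of heterochromatin and DNA methylation, 4 rose and 2 fell (4 and 3 adjusted over the list alone; adjusted p = 0.95). The methylation genes Dnmt3l and Dnmt3a rose by 0.67 and 0.58 and the chromatin remodeller Atrx by 0.60, and Kmt5c changed by -0.44.

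Markers of fibroblasts, which include the feeder cells, were higher in ntES cells. Of 39 measured, 11 rose and 1 fell (18 and 1 adjusted over the list alone), and 36 lay above 0, with a median of 0.29. Timp3, Ccn2, Postn and Ccn1, all genes of the extracellular matrix and its regulation, rose by 0.89, 0.77, 0.74 and 0.63. The member that fell, Thy1, changed by -0.60 and was named after its values were seen. Camera gave an adjusted p of 1.44e-06, and the adjusted p = 0.931 with an estimated correlation. Of 23 endoderm markers, 7 rose and none fell (12 and 1 adjusted over the list alone). Krt19, the basement membrane collagen Col4a1, Pth1r and Gata6 rose by 0.54, 0.44, 0.44 and 0.32. That list had an adjusted p of 0.00185, and an adjusted p = 0.232 with an estimated correlation. Of 18 immune markers, the lysozyme gene Lyz2 rose by 1.19 and Cd3e by 0.50, and none fell (6 and 1 adjusted over the list alone). The adjusted p was 0.00618, with an adjusted p = 0.457 with an estimated correlation and 0.271 without dim probe sets.

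Other lineage lists had members that changed in both directions, and did not pass camera's test. Of 23 trophectoderm markers, 7 rose and 5 fell (8 and 5 adjusted over the list alone; adjusted p = 0.425 by camera and 0.0185 by fry), with Krt18 and Krt8 up by 1.69 and 1.61 and the T-box gene Eomes at -1.11. Of 25 mesoderm markers, 3 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.196), with Wnt5a up by 0.41 and Tbx20 at -0.46. Of 24 neurectoderm markers, 2 rose and 4 fell (2 and 4 in the same directions, adjusted over the list alone; adjusted p = 0.359). Nnat, Tubb3 and Map2 changed by -0.83, -0.66 and -0.44, and Neurod1 rose by 0.52. Of 27 genes of the mesenchymal to epithelial transition, 7 rose and 3 fell (7 and 3 in the same directions, adjusted over the list alone; adjusted p = 0.152). The keratins Krt8 and Krt18 and the growth factor Tgfb2 rose, the last by 0.38, while the epithelial splicing regulator Esrp1 changed by -0.93. This list passed as higher without ntES replicate 1 (adjusted p = 0.029) and without the 2 arrays of narrowest spread (adjusted p = 0.046).

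Of 42 cell cycle genes, 6 fell and 2 rose (7 and 2 adjusted over the list alone). Cenpe, a kinetochore motor, Foxm1, Cdc25c and Mad2l1, all of the mitotic phase, changed by -1.11, -0.64, -0.49 and -0.44. The list was lower (adjusted p = 0.00618), with an adjusted p = 0.965 with an estimated correlation, and did not pass without ntES replicate 1 (adjusted p = 0.434), after quantile normalization (adjusted p = 0.0519) or without dim probe sets (adjusted p = 0.196). Of 27 genes of the p53 response and growth arrest, 4 rose and 5 fell (6 and 6 adjusted over the list alone; adjusted p = 0.5). Gadd45a, Perp and Psrc1 changed by -0.99, -0.81 and -0.57, and Pmaip1, which promotes cell death, rose by 0.84. Of 28 stress and immediate early genes, 5 rose and 2 fell (5 and 2 in the same directions, adjusted over the list alone; adjusted p = 0.807), with the chaperones Hsph1 and Hspa1a up by 0.72 and 0.44, Bnip3 up by 0.57 and Egr1 at -0.68. Of 36 cytosolic ribosomal protein genes, Rpl22 rose, by 0.61, and none fell (1 and 0 adjusted over the list alone; adjusted p = 0.441), and without ntES replicate 1 that list passed as higher (adjusted p = 0.00743). Median, mean and camera's direction differed in sign for the primed epiblast, p53, heterochromatin, glycolysis, neurectoderm and stress lists, none of which passed.

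**Figure D2:**
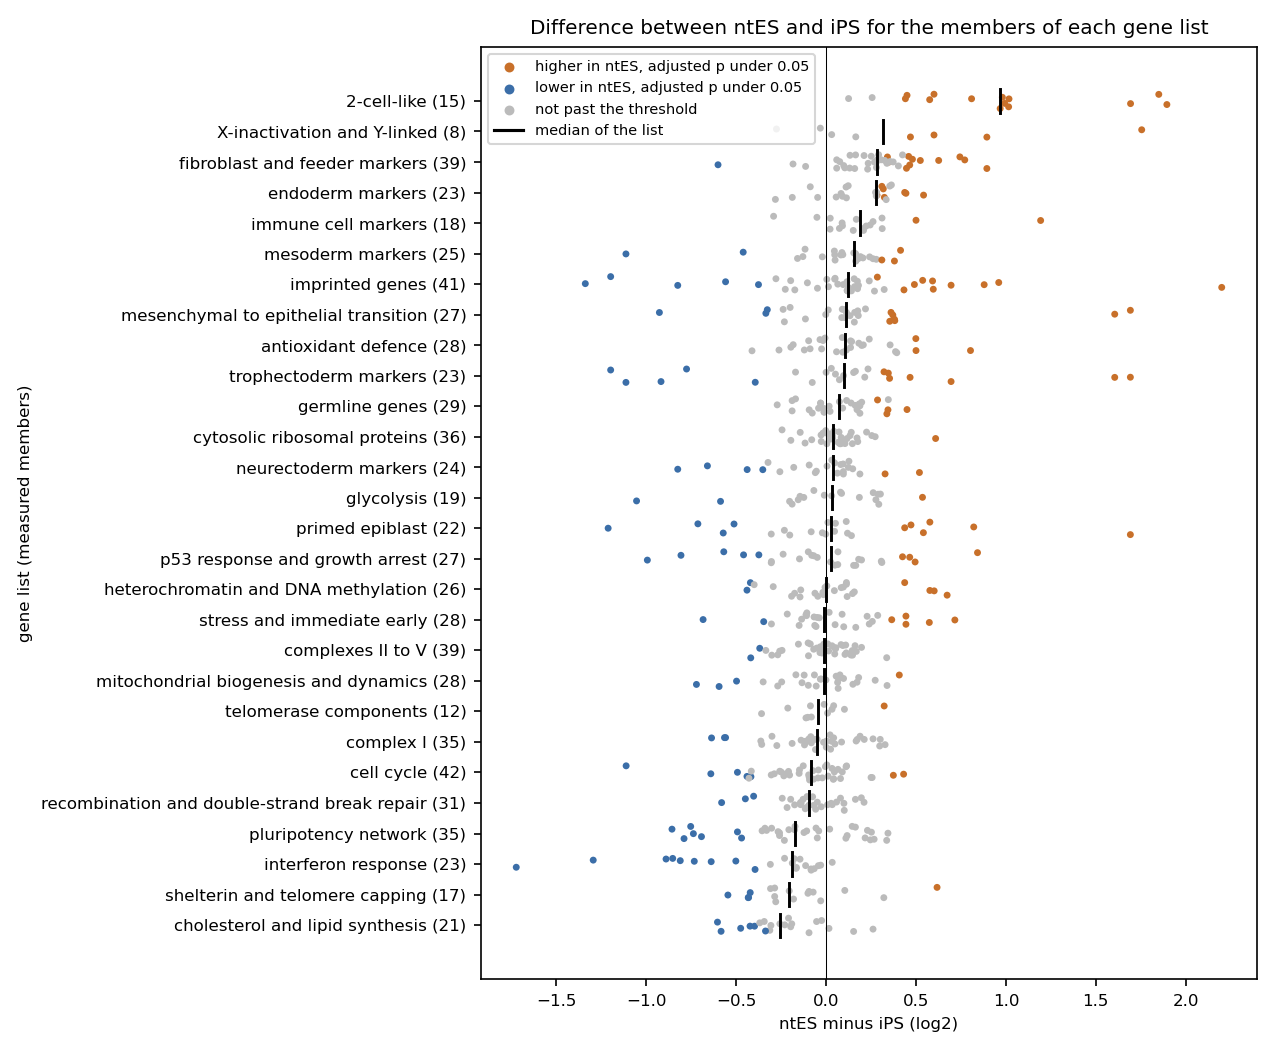
Difference between ntES and iPS cells (log2, horizontal axis) for each measured member of 28 gene lists, with called members in colour and the list median as a black bar. The 2-cell-like list has the highest median, 0.97, and the list of cholesterol and lipid synthesis the lowest, -0.26.

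In all, 11 of 28 lists passed with the preset correlation and 0 with an estimated one, where 2 had an unadjusted p under 0.05. By fry, 6 lists passed, namely the 2-cell-like, endoderm, immune, interferon, trophectoderm and X and Y lists. Exchanging arrays between the groups also gave between 5 and 21 lists with the preset correlation.

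Neighbouring genes were compared after the values were seen. Running medians over 41 genes passed the permuted threshold of 0.19 in 840 of 8869 windows, which merged into 14 segments on 9 chromosomes, with 10 lower and 4 higher in ntES cells. The segments held 1476 of the 9669 genes in the GRCm38.p6 gene order. The strongest fall spanned 178 genes of chromosome 12, from Gphn to Tmem196 (median -0.39), with 98 called lower and 9 higher. Chromosome 6 had 257 genes from Spr to Resf1 (median -0.26, 105 lower and 8 higher). Chromosome 8 had 171 genes from Cbfb to Itgb1 (median -0.26), and chromosome 19 had 207 genes from Cpt1a to Stambpl1 (median -0.25). The higher segments included 67 genes of chromosome 3 from Sec24b to Wls (median 0.35) and 104 genes of chromosome 4 from Crocc to Agrn (median 0.25). That of chromosome 3 had 29 genes called higher and 13 lower. It overlapped a lower segment from Frrs1 to Ppp3ca (median -0.24), so some genes lay in both. The segments were chosen by the differences themselves, so falls were also counted in genes held out while segments were found from every other gene. Of 603 held-out genes in lower segments found this way 268, or 44.4%, fell, against 760 of 8925, or 8.5%, outside the segments. Esrrb, Gstz1 and Coa8 lay in the chromosome 12 segment, Usp18, Ldhb, Slc2a3, Ndufa9 and Rad52 in that of chromosome 6, and Acd, Terf2, Mvd and Tomm20 in that of chromosome 8. Without the genes of these segments, 967 probe sets were higher and 850 lower.

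**Figure D3:**
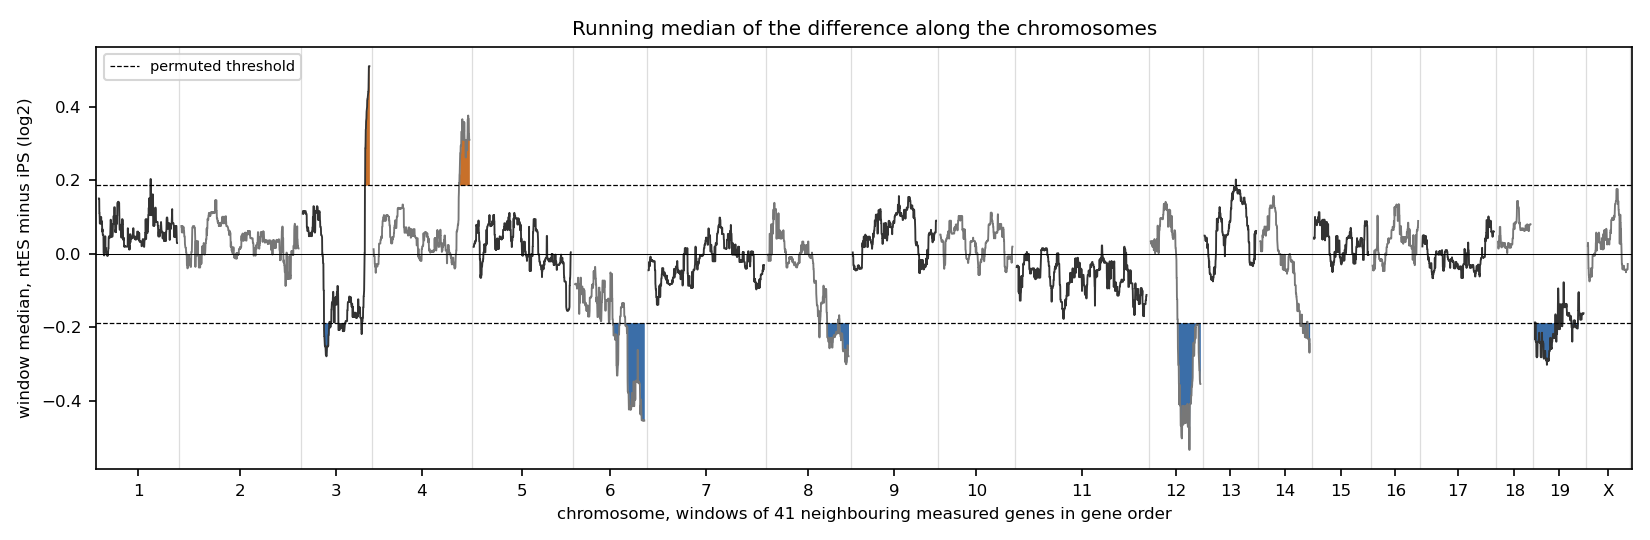
Median difference between ntES and iPS cells (log2, vertical axis) in running windows of 41 neighbouring measured genes along the chromosomes (horizontal axis, gene order), with the permuted threshold of 0.19 as dashed lines and the parts beyond it in colour. Windows beyond the threshold include blue stretches on chromosomes 6, 8, 12 and 19 and orange ones at the ends of chromosomes 3 and 4.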

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

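The settings without the genes of shifted segments, without the 2 arrays of narrowest spread, and with quantile normalization together with an estimated correlation were chosen after seeing the data. The main count of 2643 probe sets (1212 higher, 1431 lower) became 7035 (3339, 3696) after quantile normalization, 15271 (9307, 5964) with array weights, whose fit stopped before it converged, 703 (334, 369) with an unmoderated linear-model test and 1150 (520, 630) at an adjusted p of 0.01. A variance trend with robust priors gave 3703 (1866, 1837). Without the genes of shifted segments, 850 were lower and, with a 2-fold change, 27 were lower. Leaving out 1 array at a time gave 1014 to 5044 calls, the lowest without ntES replicate 2 and the highest without ntES replicate 3, with 469 to 2259 higher and 545 to 2785 lower. The corresponding 2-fold counts were 132 to 151, with 67 to 106 higher and 41 to 69 lower. Without iPS replicate 1 there were 1134 calls and without iPS replicate 2 there were 1042. The cause of these moves was not tested, apart from the stricter threshold and the fewer probe sets.

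Lists past the threshold numbered 11, against 0 with an estimated correlation, 5 without dim probe sets, 0 after quantile normalization with an estimated correlation, and 10 to 13 without 1 array. Of the 9 fixed genes measured, 4 passed, against 7 after quantile normalization, 2 after median centring and 0 to 4 without 1 array, with 0 without iPS replicate 2 and without ntES replicate 2. With array weights, in the fit that did not converge, all 9 passed, also Terc (adjusted p = 0.00148) and Myc (0.0328). With the unmoderated test none passed, and the lowest adjusted p was that of Tert (0.0808). The leading principal component held 63.9% without dim probe sets. None of the 112 called genes that the naming rule took changed direction under any setting that tested it. Their groups did not overlap, so leaving out or reweighting arrays, or changing the variance estimate, could not have reversed them. After quantile normalization 112 kept their call, after median centring 104 did, and with the unmoderated test 44 did.

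Deviations from the group means gave no sign that the replicate numbers pair the arrays, with correlations of -0.43, -0.10 and -0.72 between arrays of equal number. Between iPS replicate 3 and ntES replicate 1, the 2 arrays of narrowest spread, the correlation was 0.69. Differences in array spread could thus hide a pairing, and none is excluded. With the replicate block there were 1983 calls (865 higher, 1118 lower), of which 1890 were among the main calls, 137 with a 2-fold change, 11 lists and 3 fixed genes. Under the block the recombination list lost its call (adjusted p = 0.0637) and that of the mesenchymal to epithelial transition gained one (adjusted p = 0.0203). No array correlated best with the array of equal number. Dim probe sets, near the background of the arrays, limit what can be measured for the 2-cell-like and lineage genes.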

Other observations

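The test of segments after quantile normalization was set before its value was seen. The other tests, of copies, sequence variants, the feeder list, gene families, array spread at dim probe sets and other splits of the arrays, were chosen or given their bounds only after the result was seen.

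Neighbouring genes moved together in 14 segments, with medians from -0.39 to 0.35. On every one of them the 3 ntES arrays lay on one side of the 3 iPS arrays once each array was set against the genes outside. The segments were chosen by this same difference, so the separation is no separate evidence. Within a group, ntES replicate 1 minus replicate 3 also had 39 windows past its own threshold of 0.09, with a largest median of 0.12 against 0.53 between the groups. Its window medians correlated at -0.35, across windows, with those between the groups, and iPS replicate 1 minus replicate 2 had 4 windows past its threshold. All 14 segments again held a window past the permuted threshold after quantile normalization. Differences were centred within brightness classes both times, which already takes out most of what quantile normalization changes. The repeat was therefore likely to pass and decides nothing further about array spread or brightness. A different number of copies of these segments in the cultures is a candidate explanation that these values leave open. In segments found from every other gene, on chromosomes 3, 4, 6, 8, 12, 14 and 19, 18 of 18 medians of the genes held out kept the direction, but shared regulation of neighbours would give this too, and the segments of chromosomes 1 and 13 were found in neither part. Of the 14 segments, 6 reached the last measured gene of their chromosome (permutation p = 0.0001, one-sided, the smallest that 10000 random placements can give). Segments were joined from whole windows, so a shift that stops short of the last gene can be drawn out to it. The p can therefore overstate how often shifts reached an end, and this count was chosen after the segments were seen. It decides nothing about copies. In all ntES cells, a change from 2 copies to 1 would be -1 and from 2 to 3 would be 0.58 without array compression. The same changes in all iPS cells would have these sizes with the opposite sign. No segment median was as large as 0.58 in either direction. Array compression or a change in part of the cells would give less, so this decides nothing. Copies, sequence variants under the probes (78.5% of genes lay in the direction in the median segment) and shared regulation cannot be told apart here, since no sequence or copy number was at hand.

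Higher fibroblast and feeder genes in ntES cells may come from a larger share of feeder RNA in those cultures. Their members moved unequally (weighted squared deviations of 5.79 per degree of freedom around a weighted mean of 0.26), but this decides nothing, because genes that stem cells also express would shift less. Among abundant members, Timp3, Ccn2 and Postn rose by 0.89, 0.77 and 0.74 and Col1a1 read 10.97 in iPS and 11.43 in ntES cells, while Vim, Fn1 and Bgn differed by 0.10, 0.13 and 0.06. Thy1 changed by -0.60, which a larger feeder share alone would not give if feeders express that gene more than the stem cells do. A feeder share and a change within feeder or stem cells cannot be told apart, since the level of these genes in each kind of cell was not measured. Whether feeder RNA also bears on the lower pluripotency genes, on Meg3, or on Xist and the Y-linked genes was not tested.

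Among the 2-cell-like genes, the members without a family copy on the list, Zfp352, Arg2 and Tmem92, had a median of 1.02. Signal shared with other list members would not give this for them. Copies outside the list were not checked, so signal shared within gene families stays open as a cause of the rise. After quantile normalization 14 of 15 members passed as higher, against 30.1% of all probe sets in either direction. That setting calls more probe sets throughout, so the count does not exclude a part played by array spread at dim probe sets. A larger fraction of cells in the 2-cell-like state in the ntES cultures, or a higher level in each cell, could give such values, and bulk arrays do not separate these. The reprogramming route and the cell line stay open as biological differences and were not tested against each other.

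The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2643 probe sets, 137 with a 2-fold change, against at most 0 in the others, so that 1 of 10 splits reached each count. For gene lists the real split gave 11 and the others up to 21, and 7 of 10 splits, the real one included, gave as many. Each other split keeps part of the difference between the groups, and what gave its lists was not tested.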
